A study of Mus musculus with 6 samples.

How the data were processed

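RNA from 6 libraries of sorted mouse spleen B cells was measured by sequencing, 1 library for each of 6 groups: MZ from wt, Spp1-/- and Scid Spp1-/- mice, FB from wt and Scid Spp1-/- mice, and IgMlo CD23lo from Scid Spp1-/- mice. Per the labels' protocols, spleen cells were depleted with beads against CD3, CD4 and CD8, sorted by flow cytometry and sequenced from total RNA with standard Illumina libraries. The mice were untreated, and the labels give neither replicate numbers nor whether sorts of 1 genotype shared spleens. The submitters' processing notes name Trim Galore 0.4.0, STAR 2.4.1d, HTSeq 0.6.1p1 and edgeR. Strand use, genome build and annotation are not given in the sources used here.

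The deposited table of raw counts holds reads per gene for 38561 genes, with HTSeq's 5 summary lines below them, in the format of the HTSeq that the submitters' processing notes name. Reads in no gene were 11.4% to 15.2% of each library and ambiguous reads 0.698% to 0.723%, and both were left out. A deposited table of normalized signal, per the submitters' column names, held 14961 genes. Each of its values was a raw count times 1 constant per library (0.930 to 1.08, all 100% whole within 0.01 read once divided by it), and it held the genes whose highest count was at least 10. It was used for an alternative only. Symbols and positions came from GENCODE M21 (GRCm38) by gene ID, which matched 36723 genes. Ighd was not in the count table. Genes with near copies, such as Hba-a1 and Hba-a2, Ifit3 and Ifit3b, the V segments and pseudogenes, are uncertain, as are overlapping and antisense genes.

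Libraries held 39598856 to 45937775 reads counted to genes, so a count of 3 is under 0.1 CPM. Genes were filtered with edgeR's filterByExpr, which kept 14781, scaled with TMM (factors 0.971 to 1.05) and fitted with the additive model of genotype and sort over all 6 libraries in edgeR 4.0.16 on R 4.3.3, with quasi-likelihood F tests, 1 residual and 3.81 prior degrees of freedom, a biological coefficient of variation of 17.2% and Benjamini-Hochberg adjustment at an FDR of 0.05. Standard errors are the log2 fold change over the square root of F. The 6 tests were MZ versus FB, Scid Spp1-/- versus wt, Spp1-/- versus wt in MZ, Scid Spp1-/- versus Spp1-/- in MZ, and IgMlo CD23lo versus FB and versus MZ. Single libraries were compared by the log2 ratio of TMM CPM with a prior count of 2, counted at a log2 of at least 1 with at least 5 CPM in 1 library, with no p. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

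The 31 gene lists (409 genes), the tests, the naming rule and most alternatives were fixed before the data were examined. The lists were marginal zone, follicular, B-1, age-associated, plasma, immature or transitional, germinal centre and regulatory B cells, proliferation, interferon response, immediate early genes, heat shock, activation and NF-kB, B cell receptor signalling, p53 targets, non-homologous end joining, osteopontin receptors, genes near Spp1, MHC class II, Toll-like receptors, Notch pathway, migration receptors, and markers of T cells, NK cells, macrophages, dendritic cells, neutrophils, erythroid cells, platelets, stroma and sex. List p-values were adjusted over all genes and, separately, over the list alone. The median of each list with at least 5 members was placed among 10000 random lists, each drawn from the 100 genes nearest in expression to each member. List members with 0 counts on 1 side were also set to a bound from 3 counts.

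Genes were named by rule: the 12 largest rises and 12 largest falls among genes that passed with at least 10 CPM in the higher group, and for MZ versus FB and Scid Spp1-/- versus wt with the same direction in both direct comparisons, without V, D, J and T cell receptor segments, predicted genes, pseudogenes and genes with no symbol. Where fewer than 6 genes passed, the direct comparison gave the names without a p. List members served as examples by size, and Cr2, Cd9, Cd1d1, Fcer2a, Ighm, Ighd, Spp1 and Prkdc were to be given always. Some list members of known role that were not the largest, such as Bcl6, S1pr2, Aicda, Mki67, Derl3 and Fas, were named after their values were seen.

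Isotype shares are reads of each constant gene over all heavy chain constant reads other than Ighd, with exact (Clopper-Pearson) 95% intervals. V segment diversity is the exponential of Shannon entropy at 39098 Ighv and 85042 Igkv reads per library. In simulated data with the real library sizes and 1 mean profile for all libraries, 100 genes per comparison were changed at each of 2 sizes. The fit was tested on these data. It recovered 80% of changes of log2 1 for MZ versus FB (14201 genes), 72% for Scid Spp1-/- versus wt (14148), 55% for Spp1-/- versus wt (14192), 53% for Scid Spp1-/- versus Spp1-/- (14174), 44% for IgMlo CD23lo versus FB (14141) and 56% versus MZ (14162). At log2 2 it recovered 94% to 100%. Unchanged genes were 1.43% to 6.79% of calls. Real differences between sorts and genotypes were not simulated, so recovery in the real data may be lower.

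The alternatives were DESeq2 size factors, upper quartile scaling, no low-count filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), immunoglobulin genes removed, glmTreat at a log2 of 0.58, the model without its genotype term (over 5 libraries, without IgMlo CD23lo) or without its sort term (over the 4 wt and Scid Spp1-/- MZ and FB libraries), fits without a lone library, a prior count of 0.5, CPM minimums of 1 and 20, and inverse Simpson diversity. Chosen after seeing the data were reads recovered from the scaled table and the subtraction from Scid Spp1-/- FB of a share of IgMlo CD23lo, taken as the median excess of 9 germinal centre genes at least 4 times higher in IgMlo CD23lo than in wt FB, which left out Bcl6.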

Results

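RNA was sequenced from B cells sorted from mouse spleen in 6 libraries, 1 library per group, all of BALB/c strain. The cells were CD19+, B220+ and CD93- and were parted by surface IgM and CD23. IgM-high CD23-low cells, named MZ in the labels and matching the textbook surface of marginal zone B cells, came from wild-type (wt), Spp1-/- and Scid Spp1-/- mice. IgM-low CD23-high cells, named FB in the labels and matching the textbook surface of follicular B cells, came from wt and Scid Spp1-/- mice. IgM-low CD23-low cells, written IgMlo CD23lo here, came from Scid Spp1-/- mice alone. Spp1 encodes osteopontin, a secreted phosphoprotein. The scid mutation lies in Prkdc, which encodes a kinase that takes part in joining V(D)J segments when antigen receptor genes are assembled. Reads counted to genes came to 45937775 in wt MZ, 45772015 in wt FB, 43360592 in Spp1-/- MZ, 40372949 in Scid Spp1-/- MZ, 39598856 in Scid Spp1-/- FB and 44516752 in IgMlo CD23lo.

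No group had a replicate. Each test used an additive model of genotype and sort over the 6 libraries, whose 1 residual degree of freedom is the difference between the MZ to FB differences of the wt and the Scid Spp1-/- mice. The resulting p-values measure the spread between these libraries alone, which may be technical, and where both sorts of a genotype came from the same spleens they hold no mouse-to-mouse spread for a genotype comparison. The Spp1-/- MZ and IgMlo CD23lo libraries were assumed to vary like the others. A fitted log2 fold change shares 1 MZ to FB difference across genotypes, so it can differ from the ratio of 2 libraries. Values after ± are standard errors of the fit, and intervals on counts cover counting error only.

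The targeted gene, Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050 in GRCm38), had 54 counts in wt MZ, or 1.17 CPM (counts scaled to the normalized library total) with an exact Poisson 95% interval of 0.882 to 1.53. In wt FB it had 5 counts. Spp1-/- MZ had 0 counts, which made Spp1 at least 17.0-fold lower there than in wt MZ against a floor of 3 counts. Transcripts of 11 pancreatic enzymes, a group chosen after its values were seen, also differed between these libraries, with 307 counts in wt MZ, 105 in wt FB, 4 in Spp1-/- MZ, 63 in Scid Spp1-/- MZ, 28 in Scid Spp1-/- FB and 27 in IgMlo CD23lo, and whether the Spp1 reads of wt MZ came from B cells was not determined. Scid Spp1-/- MZ had 1 count, and the ratio of wt MZ to it was 46.3 with a counting interval of 7.96 to 1861. Scid Spp1-/- FB had 2 counts, and the ratio of wt FB to it was 2.23 (0.365 to 23.4), so a loss was not detectable in FB at this depth. IgMlo CD23lo had 3 counts, up to 0.187 CPM. Which part of Spp1 the knockout removed is not given in the labels. Prkdc (ENSMUSG00000022672, chromosome 16, 15637866 to 15842235) had 92.1 CPM in wt MZ, 78.1 in wt FB, 95.4 in Spp1-/- MZ, 78.9 in Scid Spp1-/- MZ, 76.9 in Scid Spp1-/- FB and 79.5 in IgMlo CD23lo, and its transcript level does not test a point mutation.

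The MZ and FB sorts were compared across the wt and Scid Spp1-/- mice to ask which genes part the 2 populations in both genotypes. Genes of marginal zone B cells were higher in MZ. Of 15 measured members of that list, 8 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 of 1.72. Myof, a membrane repair protein, rose by log2 4.77 ± 0.36, Cd9, a tetraspanin of marginal zone B cells, by 4.01 ± 0.62, from 1.55 CPM in wt FB to 62.7 in wt MZ, and Cd1d1, which presents lipid antigens, by 2.23 ± 0.13. Cr2, the complement receptor CD21, stood at log2 1.10 ± 0.21 without passing, at 3178 CPM in wt MZ and 1145 in wt FB, and the sphingosine phosphate receptor S1pr3 stood at 2.71 ± 0.51 without passing. Ighm, the heavy chain of the sorted IgM, rose by 1.40 ± 0.23, and Ighd was not analysed here. Of 11 follicular B cell genes, 5 fell and 0 rose (8 and 0 over the list alone). Fcer2a, which encodes the CD23 used in the sort, had log2 -3.31 ± 0.11, the chromatin organiser Satb1 -1.26 ± 0.09 and the interleukin-4 receptor Il4ra -1.36 ± 0.09.

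Germinal centre genes were lower in MZ, with 6 of 10 falling and 0 rising (7 and 0 over the list alone). Bcl6, the repressor that directs the germinal centre programme, had log2 -1.90 ± 0.12, Rgs13, a regulator of G protein signalling, -3.58 ± 0.25, Gcsam -3.54 ± 0.27 and Mybl1 -2.92 ± 0.13. These genes were very high in the IgMlo CD23lo library. With a 7.18% share of that library subtracted from Scid Spp1-/- FB, Bcl6 still passed at -1.71. Bcl6 was not among the 9 germinal centre genes that set the share. Rgs13 and Mybl1 (-1.38) stayed lower in MZ but no longer passed. Gcsam (0.43), Nuggc (1.51) and Basp1 (0.58) changed sign and did not pass. All of these but Bcl6 helped set the share, so the subtraction weakens their fall by itself. In wt alone, with no p, 6 of 10 genes were at least 2-fold lower in MZ and 2 at least 2-fold higher.

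Among lists of other B cell states, 5 of 13 B-1 cell genes rose in MZ, among them Bhlhe41 at log2 1.98 ± 0.09 and the phosphatase Ptpn22 at 2.13 ± 0.23, and 0 fell (7 and 0 over the list alone). Plasma cell genes rose in 4 of 17 cases and fell in 0 (7 and 0 over the list alone), led by Jchain, the joining chain of secreted IgM, at 2.91 ± 0.47 and Prdm1, the plasma cell regulator Blimp-1, at 2.63 ± 0.24. Of 12 age-associated B cell genes 2 rose, Fcrl5 at 2.51 ± 0.27 and Cd80 at 2.03 ± 0.24, and 0 fell (8 and 1 over the list alone). Of 21 immediate early genes 6 fell, among them Egr3 at -1.56 ± 0.23 and Egr1 at -1.40 ± 0.10, and Myc rose by 0.97 ± 0.09 (10 and 1 over the list alone). Migration receptors went both ways, as S1pr1 rose by 0.93 ± 0.11 and 4 of 16 fell, among them Cxcr4 at -1.86 ± 0.13 and Ccr7 at -0.94 ± 0.15 (4 and 8 over the list alone). Tlr3, a sensor of double-stranded RNA, rose by 2.79 ± 0.19 as 1 of 10 Toll-like receptor genes (7 over the list alone). In the Notch pathway 1 of 15 genes rose and 2 fell (3 and 3 over the list alone), the latter being the ligand Dll1 at -3.60 ± 0.52 and Lfng at -1.67 ± 0.15. Of 18 activation and NF-kB genes, Cd80 and Cd86 rose and Cd69 and Cd83 fell (3 and 4 over the list alone). Outside the fixed lists, Sel1l3 (5.34 ± 0.27), the protease inhibitor Serpine2 (5.01 ± 0.32) and the plexin Plxnd1 (4.25 ± 0.18) were among the largest rises, and Rgl1 (-4.73 ± 0.39) and Ndrg1 (-3.66 ± 0.15) among the largest falls.

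Smaller numbers passed elsewhere. Cd274 and Entpd1 rose among 9 regulatory B cell genes, Cd44 and Itgb1 among 8 osteopontin receptor genes, Ly6a among 28 interferon response genes and Cd81 among 19 B cell receptor genes, where Pik3cd fell. Ciita, the activator of MHC class II genes, fell among 10 of its list, Mcm5 among 25 proliferation genes and Lrrc8b among 13 genes near Spp1. In the transitional list Cd24a rose and Lef1 fell, of 10 measured. Over each list alone the numbers higher and lower were 2 and 1 for regulatory B cells, 3 and 1 for osteopontin receptors, 7 and 0 for interferon response, 2 and 2 for B cell receptor signalling, 0 and 2 for MHC class II, 0 and 1 for proliferation, 3 and 2 near Spp1 and 2 and 2 in the transitional list. The lists of heat shock genes (10 measured), p53 targets (17) and non-homologous end joining (10) had 0 members passing in edgeR, 0 also over each list alone. Markers of other cells were given by Lck, which fell among 16 T cell genes, and by Cd68 and Ly6c2, which rose among 12 macrophage genes. The lists of NK cells (7 measured), dendritic cells (10), neutrophils (10), erythroid cells (10), platelets (2) and stroma (5) had 0 passing, against 1 NK and 1 dendritic cell gene over those lists alone. Xist, the 1 sex-linked gene measured, rose by log2 0.76.

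By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 599 of 14781 genes passed an FDR of 0.05, 367 higher and 232 lower in MZ, and 597 of them went the same way in both genotypes. Genes whose differences disagree between the genotypes get a large error in this fit, so that agreement is largely set by the test. The count was 989 with DESeq2, 1045 with limma-voom, 377 with upper quartile scaling, 396 after subtraction of the IgMlo CD23lo share, 152 against a log2 threshold of 0.58 and 38 without the genotype term and the IgMlo CD23lo library, against 611 without that library alone. Compared directly, wt MZ and FB differed at least 2-fold in 706 genes (494 higher, 212 lower) and Scid Spp1-/- MZ and FB in 717 (428 higher, 289 lower), with no p. Across 9903 genes the 2 direct comparisons had a Pearson correlation of 0.674 and a Spearman correlation of 0.595, though genes are not independent replicates. Of 843 of these genes that were past 2-fold between wt MZ and FB, 738 had the same sign in Scid Spp1-/-. The plot of marker levels shows the genes that define the sorts.

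**Figure D1:**
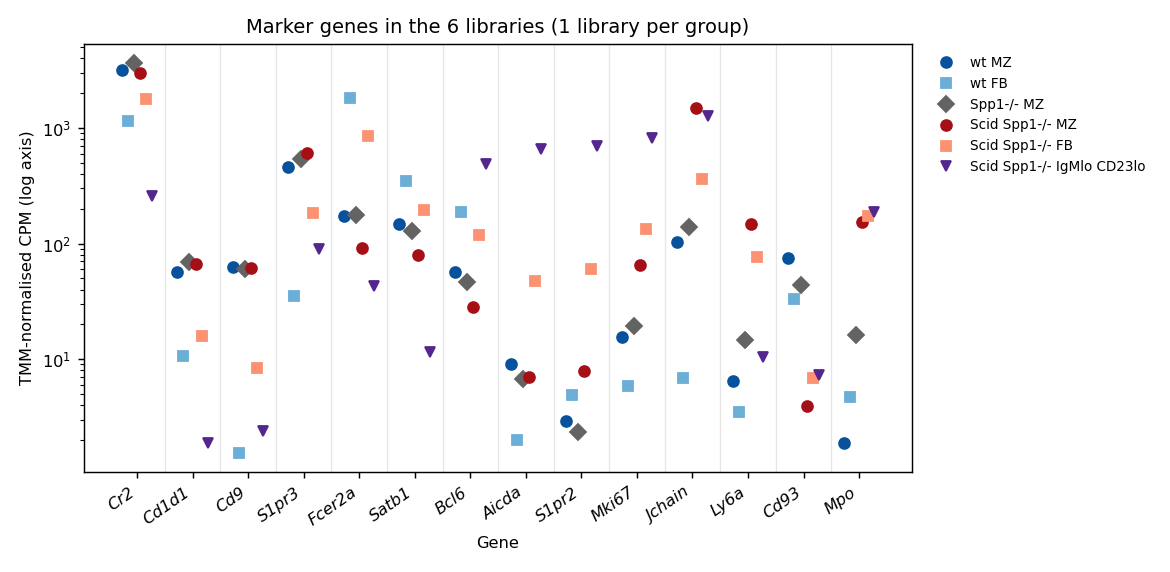
Normalized level (CPM, log axis) of 14 marker genes in the 6 libraries, 1 point per library. Fcer2a was at 1825 CPM in wt FB and 43.2 in IgMlo CD23lo, Aicda reached 656 CPM in IgMlo CD23lo, and Mpo was at 155 CPM or more in the 3 Scid Spp1-/- libraries.

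Scid Spp1-/- and wt B cells were compared over MZ and FB together to ask what the combined genotype changes in both sorts. Switched antibody genes were far higher in Scid Spp1-/-. Ighg1, the IgG1 heavy chain, rose by log2 6.36 ± 0.19, from 2.13 to 145 CPM in MZ and from 4.01 to 386 CPM in FB, and Ighg2c, which may take reads of the BALB/c gene Ighg2a, rose by 5.12 ± 0.13. The excess of Ighg1 over wt was 9.03% of that in IgMlo CD23lo in FB and 3.30% in MZ. After subtraction from Scid Spp1-/- FB of an IgMlo CD23lo share of 7.18%, the median excess of 9 germinal centre genes, Ighg1 stood at 5.23 ± 0.44 and Ighg2c at 4.44 ± 0.24, and both still passed. Plasma cell genes rose in 5 of 17 cases and fell in 0 (9 and 1 over the list alone), with Jchain at 4.73 ± 0.50 and Derl3, of the endoplasmic reticulum, at 2.03 ± 0.15. Age-associated B cell genes rose in 4 of 12 cases and fell in 0 (10 and 0 over the list alone), namely the integrin Itgax, or CD11c, at 3.52 ± 0.23, the transcription factor Tbx21, or T-bet, at 2.66 ± 0.31, Cxcr3 at 3.04 ± 0.28 and Adgre1 at 1.08 ± 0.14. Itgax is also on the dendritic cell list and Adgre1 on the macrophage list, and genes of both lists rose in this comparison too. Of 13 B-1 cell genes 4 rose and 0 fell (8 and 0 over the list alone), among them Zbtb32 at 2.25 ± 0.20 and Bhlhe41 at 0.97 ± 0.09.

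Genes of immature B cells were lower, as 4 of 10 fell and 0 rose (6 and 3 over the list alone). Cd93, the marker excluded in the sort, had log2 -3.23 ± 0.51 (74.9 to 3.96 CPM in MZ, 33.1 to 6.91 in FB), the transcription factor Lef1 -4.55 ± 0.42 and Sox4 -2.88 ± 0.37. Marginal zone genes had 0 of 15 passing, 0 also over the list alone, with Cr2 at 0.28 ± 0.21 and Cd1d1 at 0.39 ± 0.13. Compared directly, with no p, that list's median was 0.16 in MZ, with 0 members at least 2-fold apart, and 1.02 in FB, with 14 of 15 members above 0 and 9 at least 2-fold higher in Scid Spp1-/-. Of 11 follicular genes 3 fell (6 over the list alone), with Fcer2a at 173 CPM in wt MZ against 92.4 and 1825 CPM in wt FB against 858, Klf2, which restrains the marginal zone fate, at log2 -0.95 ± 0.09 and Satb1 at -0.86 ± 0.08. Bmf, a pro-apoptotic BH3 protein, had -4.28 ± 0.18, the acyl-CoA thioesterase Acot9 -5.07 ± 0.22, Arl2bp -3.21 ± 0.11 and Tnfrsf19 -4.05 ± 0.26.

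Of 10 germinal centre genes 5 rose and Bcl6 fell, at log2 -0.83 ± 0.11 (7 and 1 over the list alone). Gcsam went from 1.24 to 24.1 CPM in FB and from 0.217 to 1.73 CPM in MZ. Nuggc stood at log2 3.70 ± 0.28, Rgs13 at 3.64 ± 0.25 and Mybl1 at 2.87 ± 0.13, and in the direct comparisons the list's median was 1.60 in MZ and 3.49 in FB. Summed over the list, Bcl6 included, levels were 81.0 CPM in wt and 77.9 in Scid Spp1-/- MZ, and 217 and 413 in FB. With the IgMlo CD23lo share subtracted, Gcsam (0.16), Nuggc (0.86), Rgs13 (2.03), Mybl1 (1.29) and Basp1 (-0.19) did not pass, while Bcl6 did (-1.04). All of these but Bcl6 helped set the share, so the subtraction lowers them by itself. It also took 1454 of the 4707 Bcl6 counts of Scid Spp1-/- FB. That deepens the fall of Bcl6 by itself, so its call after the subtraction adds no support. Aicda, the deaminase of class switching and somatic hypermutation, did not pass at 1.97 ± 1.30, with 9.13 and 6.95 CPM in wt and Scid Spp1-/- MZ and 1.98 and 47.2 CPM in FB. Of 25 proliferation genes 3 rose and 0 fell (24 and 0 over the list alone), namely Cdk1 at 2.95 ± 0.46, Plk1 at 2.89 ± 0.46 and Ccnb1 at 2.59 ± 0.28. Mki67 stood at 3.25 ± 0.62 without passing. The proliferation list's direct median was 1.04 in MZ and 2.72 in FB.

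Interferon response genes rose in 6 of 28 cases and fell in 0 (16 and 2 over the list alone), with Oasl2 at log2 6.01 ± 0.40 (0.0870 to 7.89 CPM in MZ), Ly6a at 4.47 ± 0.12 and Ifi44 at 2.02 ± 0.25. Of 21 immediate early genes 4 fell, among them Egr1 at -0.80 ± 0.10, and Myc rose by 1.28 ± 0.09 (6 and 2 over the list alone). Cd83, Traf1 and Ccl22 rose among 18 activation and NF-kB genes (6 and 2 over the list alone). Hsph1 rose among 10 heat shock genes (8 over the list alone), Sesn2 among 17 p53 targets (6 and 3 over the list alone), Itgb1 among 8 osteopontin receptor genes (4 and 1 over the list alone) and Abcg3 among 13 genes near Spp1 (1 and 1 over the list alone). Havcr1 and Lag3 rose among 9 regulatory B cell genes (4 and 1 over the list alone), and of 16 migration receptors Cxcr3 rose and S1pr4 fell (3 and 3 over the list alone). Over all genes in edgeR, 0 members passed of non-homologous end joining (10 measured), Notch (15), MHC class II (10), Toll-like receptors (10) and B cell receptor signalling (19). Over each list alone, 0 passed in the first 3, 2 higher and 1 lower among Toll-like receptors, and 1 each way in B cell receptor signalling.

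Transcripts of other blood cells were also higher in both Scid Spp1-/- sorts, beside these gene groups. Of 10 neutrophil genes 8 rose and 0 fell (9 and 0 over the list alone). Mpo, myeloperoxidase of granulocyte precursors, was at 1.87 CPM in wt MZ, 4.75 in wt FB, 155 in Scid Spp1-/- MZ and 171 in Scid Spp1-/- FB, and Elane stood at log2 5.86 ± 0.59. Of 10 erythroid genes 9 rose and 0 fell (9 and 0 over the list alone), with the haemoglobin gene Hbb-bs at 3.33 ± 0.17 and the anion exchanger Slc4a1 at 4.73 ± 0.20. Macrophage genes rose in 6 of 12 cases (11 over the list alone), led by Lyz2 at 4.63 ± 0.56, and 2 of 7 NK cell genes (3 over the list alone) and 2 of 10 dendritic cell genes (6 over the list alone) rose. Among 16 T cell genes 0 rose and Cd2 fell (9 and 1 over the list alone). Cd3e, Cd4 and Cd8a stayed under 2 CPM in every library. Platelet, stromal and sex-linked lists had 0 passing in edgeR, against 1 platelet and 1 sex-linked gene over those lists alone.

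In this comparison 556 genes passed the quasi-likelihood test, 333 higher and 223 lower in Scid Spp1-/-, all 556 with the same direction in MZ and FB. A gene whose MZ and FB ratios disagree gets a large error in this fit, so that agreement is largely set by the test. The count was 1164 with DESeq2, 1372 with limma-voom, 989 without the low-count filter, 292 with upper quartile scaling, 282 after subtraction of the IgMlo CD23lo share and 174 against a log2 threshold of 0.58. Without the sort term, over the 4 wt and Scid Spp1-/- MZ and FB libraries, it was 0 in edgeR, with 1681 genes at an unadjusted p under 0.05, against 517 in those libraries with the term. Compared directly, 552 genes differed at least 2-fold in MZ (345 higher) and 692 in FB (517 higher). These 2 comparisons had a Pearson correlation of 0.737 across genes and a Spearman correlation of 0.672, and 594 of 655 genes past 2-fold in MZ, with at least 5 CPM in any of the libraries compared, had the same sign in FB. Of the 655, 552 reached 5 CPM in an MZ library and the others only in FB, where a high Scid Spp1-/- level favours a positive ratio. Of 29 lists with at least 5 members, 18 had a median above the central 95% of 10000 random lists matched on expression and 3 below it. For Spp1-/- versus wt in MZ, with far fewer genes past 2-fold, the numbers were 14 and 2. Genes of 1 list can vary together between any 2 libraries, so such counts do not by themselves show a genotype effect.

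**Figure D2:**
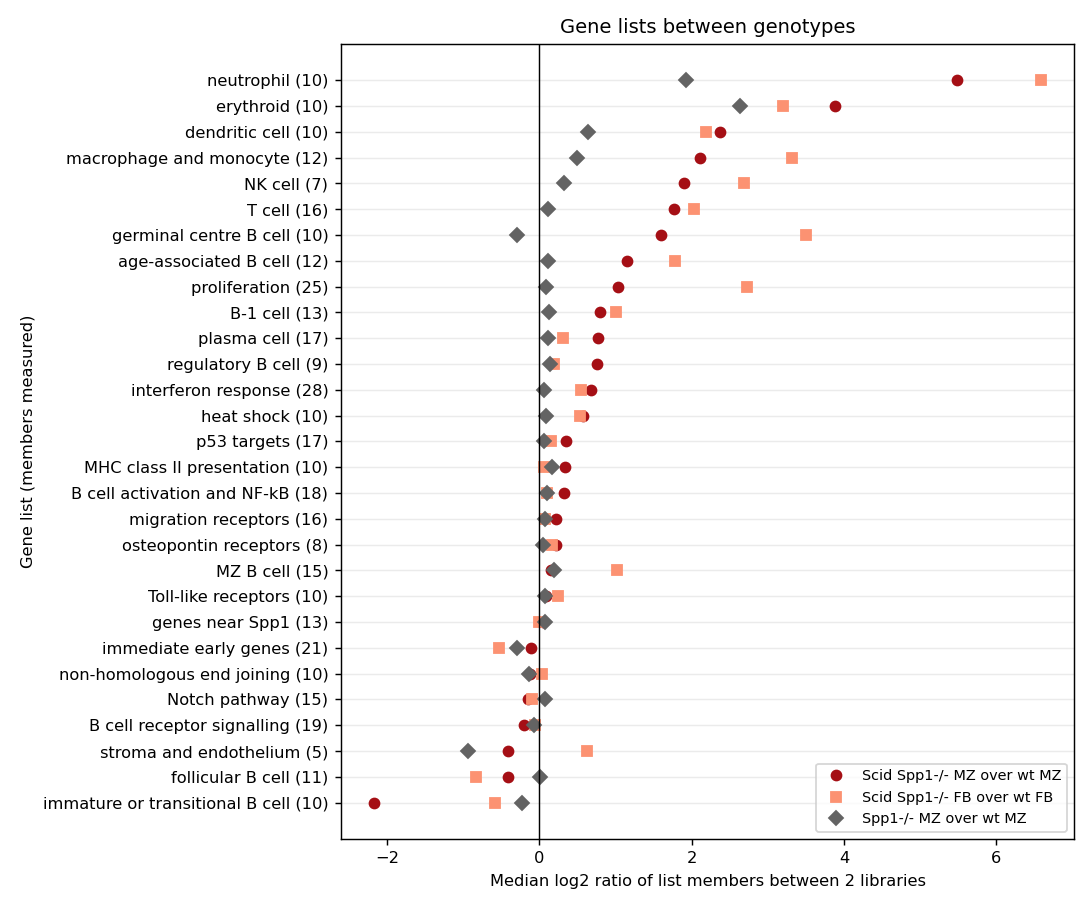
Median log2 ratio of each of 29 gene lists in 3 direct comparisons of 2 libraries, namely Scid Spp1-/- over wt in MZ, the same in FB, and Spp1-/- over wt in MZ. The neutrophil list had medians of 5.49, 6.59 and 1.93, and the germinal centre list 1.60, 3.49 and -0.29.

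Spp1-/- and wt MZ cells were compared to ask what the loss of Spp1 changes without the scid mutation. Few genes with at least 5 CPM differed 2-fold or more, and erythroid and granulocyte transcripts were among them. No gene passed the edgeR quasi-likelihood test at an FDR of 0.05, with 288 at an unadjusted p under 0.05 against 739 expected by chance. DESeq2 called 14 genes, 12 of them higher, limma-voom 1 and edgeR without the low-count filter 1. The test recovered 55% of simulated changes of log2 1 and 96% of log2 2. In that simulation all libraries shared 1 mean profile apart from the changes put in. Real libraries do not, so recovery here may be lower, and the lack of calls does not show that large changes were absent. The shortfall of p-values under 0.05 also points to a test too strict for this comparison. Of genes named below, Zhx2 at a fitted log2 of 2.96 and Arl2bp at -2.77 did not pass. Over lists alone, 9 of 10 erythroid genes, 7 of 10 neutrophil genes and 1 of 28 interferon response genes were higher, and no member of any other list passed. Compared directly, with no p, 13 genes were at least 2-fold higher and 16 lower in Spp1-/- MZ. With a CPM minimum of 1 in place of 5, 144 genes were past 2-fold. Mpo went from 1.87 to 16.2 CPM and Hbb-bs from 5.37 to 32.4 CPM. Zhx2, a zinc finger repressor, went from 12.7 to 115 CPM (log2 3.18), Abcg3 stood at log2 1.21 and Ly6a at 1.18. Arl2bp, a partner of the small GTPase Arl2, went from 123 to 17.7 CPM (log2 -2.80), the interferon-induced GTPase Gbp4 stood at -1.38 and Gas7 at -1.43. Zhx2 was at 101 CPM and Arl2bp at 12.6 in Scid Spp1-/- MZ. The BALB/c substrain of each group is not given, so loss of Spp1 cannot be told apart here from a difference in background. Against the ratio of Scid Spp1-/- FB to wt FB, which shares no library with it, this comparison had a Pearson correlation of 0.506 and a Spearman correlation of 0.427 across genes, and 68 of 78 genes past 2-fold between Spp1-/- and wt MZ, with at least 5 CPM in any of the libraries compared, had the same sign in the other ratio. Of the 78, 29 reached 5 CPM in 1 of the 2 MZ libraries, and the others only in an FB library. Genes let in by a high Scid Spp1-/- FB level tend to have a positive second ratio, so the filter may add to this agreement.

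Scid Spp1-/- and Spp1-/- MZ cells were compared to ask what the scid mutation adds where both are labelled Spp1-/-. Switched antibody genes were again higher in Scid Spp1-/-, with Ighg1 at log2 5.55 ± 0.25, Ighg2c at 5.28 ± 0.19 and Ighg2b at 2.36 ± 0.16. Ly6a stood at 3.30 ± 0.15, App, the amyloid precursor protein, at 3.40 ± 0.23 and Tent5c, a poly(A) polymerase of plasma cells, at 2.72 ± 0.15. Acot9 had -5.11 ± 0.25 and Bmf -3.34 ± 0.21. These and 3 lower predicted genes or pseudogenes, Gm8730, Gm8199 and Rplp0-ps1, whose reads may be shared with near copies, made up the 11 genes that passed (6 higher, 5 lower), named here after their values were seen where outside the rule. The count was 151 with DESeq2, 27 without the low-count filter, 7 with upper quartile scaling, 7 with reads recovered from the scaled table and 4 after subtraction of the IgMlo CD23lo share, with Ly6a higher and Acot9, Gm8730 and Gm8199 lower. The 3 switched genes no longer passed then, because their standard errors grew while the folds stayed near, with Ighg1 at 5.16 ± 0.59 (adjusted p = 0.268), Ighg2c at 5.06 ± 0.36 (0.148) and Ighg2b at 2.08 ± 0.32 (0.316). Over lists alone, 8 of 10 neutrophil, 6 of 12 macrophage, 6 of 12 age-associated, 6 of 28 interferon response, 4 of 13 B-1 cell, 4 of 17 plasma cell and 4 of 10 erythroid genes were higher. Of 10 germinal centre genes 6 were higher and 1 lower, of 10 immature or transitional genes 1 was higher and 5 lower, and of 11 follicular genes 3 were lower. Over all genes in edgeR the interferon response gene Ly6a was the 1 list member that passed. Directly, 371 genes differed at least 2-fold, 268 higher and 103 lower. Against Scid Spp1-/- FB over wt FB the Pearson correlation across genes was 0.689, and 415 of 467 genes past 2-fold between Scid Spp1-/- and Spp1-/- MZ, with at least 5 CPM in any of the libraries compared, had the same sign in the other ratio. Of the 467, 371 reached 5 CPM in an MZ library and the others only in FB, where a high Scid Spp1-/- level favours a positive ratio.

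The IgMlo CD23lo sort of Scid Spp1-/- mice was compared with the FB and MZ sorts of the same genotype to describe what sets these cells apart. Germinal centre genes were higher than in FB in 8 of 10 cases and than in MZ in 9 of 10, with 0 lower (10 and 10 over the list alone). Bcl6 rose by log2 2.11 ± 0.15 over FB and 4.01 ± 0.15 over MZ, and S1pr2, which confines B cells to the germinal centre, by 3.90 ± 0.58 and 5.88 ± 0.69. Gcsam was at 539 CPM against 24.1 in FB and 1.73 in MZ, Rgs13 at 309 CPM against 28.9 and 2.84. Aicda was at 656 CPM against 47.2 and 6.95, and its log2 of 4.51 ± 1.25 and 5.04 ± 1.69 passed neither test. Proliferation genes rose over FB in 23 of 25 cases and over MZ in 22, with 0 lower (25 and 25 over the list alone), Mki67 by 3.08 ± 0.67 and 2.98 ± 0.78.

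Genes of both other sorts were lower in IgMlo CD23lo. Of 15 marginal zone genes 12 fell against MZ, with Cd1d1 at log2 -5.22 ± 0.22, Cr2 at -3.71 ± 0.33 and Cd9 at -5.32 ± 0.92, and 8 fell and 3 rose against FB. Of 11 follicular genes 9 fell against FB, with Fcer2a at -4.36 ± 0.17 and Satb1 at -4.08 ± 0.13, and 7 fell and 2 rose against MZ. Ighm had -3.63 ± 0.34 against MZ. Interferon response genes fell in 24 of 28 cases against FB and 27 against MZ, with 0 higher (27 and 27 over the list alone), among them Ifi44 at -4.24 ± 0.39 and -4.76 ± 0.40 and Rtp4 at -3.59 ± 0.32 and -4.17 ± 0.32. Migration receptors fell in 11 of 16 cases against FB and 12 against MZ and rose in 4 and 3, with Ccr6 at -3.16 ± 0.13 and S1pr1 at -3.08 ± 0.16 against FB, where Cxcr4 was higher by 1.28 ± 0.16. Of 10 MHC class II genes 8 fell against FB and 3 against MZ, with H2-Oa at -1.62 ± 0.15 against FB. Of 15 Notch pathway genes 7 fell in each comparison, among them Lfng at -3.02 ± 0.22 and Notch2 at -2.85 ± 0.19 against FB, and of 18 activation and NF-kB genes 10 and 8 fell and 3 and 1 rose. Toll-like receptor genes fell in 4 and 8 of 10 cases. Over each list alone, 13 marginal zone genes fell against MZ and 8 against FB, 9 follicular genes against FB and 8 against MZ, 10 and 7 MHC class II genes against FB and MZ, 8 and 8 Notch genes, 11 and 12 migration receptors, 11 and 8 activation genes and 6 and 8 Toll-like receptor genes.

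Age-associated B cell genes rose in 7 of 12 cases over FB and 5 over MZ and fell in 1 and 3, with Itgax at log2 4.88 ± 0.26 and Fas, the death receptor of germinal centre cells, at 2.31 ± 0.24 over FB, while Tlr7 had -1.83 ± 0.36. Plasma cell genes went both ways (4 higher, 3 lower against FB, and 2 and 6 against MZ), as Jchain rose by 2.19 ± 0.53 over FB and Irf4 had -1.66 ± 0.19. Lig4, the ligase of non-homologous end joining, rose by 2.18 ± 0.19 over FB and Xrcc5 had -0.63 ± 0.12, and 1 of 10 genes of that list rose and 2 fell against MZ. Outside the fixed lists, the extracellular protein Reln rose by 5.19 over FB, from 9.82 to 248 CPM, and Emp2 by 5.65 ± 0.26, while Rnf144a had -5.10 ± 0.16. Of 12 macrophage genes 4 rose over FB and 2 over MZ, and of 10 dendritic cell genes 2 rose in each comparison, Itgax among them. Neutrophil and erythroid genes had 0 of 10 passing each in both comparisons in edgeR, 0 also over each list alone, with neutrophil medians of 0.03 and 0.84. By edgeR's quasi-likelihood test 3686 genes passed against FB (1791 higher, 1895 lower) and 4528 against MZ (2120 higher, 2408 lower), and against a log2 threshold of 0.58 the counts were 1457 and 2125. Direct counts at 2-fold were 2014 and 2589.

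Antibody isotypes and V segments were compared as shares of reads within each library. Heavy chain constant reads here leave out Ighd, which was not in the count table. An IgM share is therefore not a share of all heavy chain transcripts. IgM made up 99.6% of heavy chain constant reads in wt MZ and 99.5% in wt FB and in Spp1-/- MZ, 98.4% in Scid Spp1-/- MZ, 92.2% in Scid Spp1-/- FB (exact binomial 95% interval 92.1 to 92.3) and 24.2% in IgMlo CD23lo (24.1 to 24.4). Ighg1 made up 0.0154% in wt MZ (0.0125 to 0.0188), 0.0646% in wt FB (0.0554 to 0.0748), 0.0246% in Spp1-/- MZ (0.0208 to 0.0290), 0.587% in Scid Spp1-/- MZ (0.572 to 0.602), 4.57% in Scid Spp1-/- FB (4.50 to 4.64) and 53.7% in IgMlo CD23lo (53.6 to 53.9). The ratio of Ighg1 shares of Scid Spp1-/- to wt was 38.0 in MZ and 70.8 in FB, and was 67.8 and 99.7 by CPM with immunoglobulin genes left out of the total. Ighg3, the IgG3 heavy chain, made up 0.362% in wt MZ and 6.72% (6.64 to 6.80) in IgMlo CD23lo. All 6 libraries held many V segments. At equal read numbers the effective number of Ighv segments was 49.6 in wt MZ, 54.6 in wt FB, 48.4 in Spp1-/- MZ, 49.1 in Scid Spp1-/- MZ, 49.4 in Scid Spp1-/- FB and 42.5 in IgMlo CD23lo, and that of Igkv segments 48.2, 57.0, 48.0, 51.6, 56.8 and 36.7 in the same order. Ighv5-6 took the largest Ighv share in IgMlo CD23lo, in Scid Spp1-/- FB (9.58%, 9.31 to 9.86), in Scid Spp1-/- MZ (7.03%, 6.87 to 7.18) and in wt FB (7.59%, 7.33 to 7.85). Ighv2-9 led in wt MZ and Spp1-/- MZ, and Igkv1-117 took the largest Igkv share in IgMlo CD23lo and in Scid Spp1-/- FB, 5.09% (4.94 to 5.24) in the latter. V segments are near copies of one another, so reads may be split between them.

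**Figure D3:**
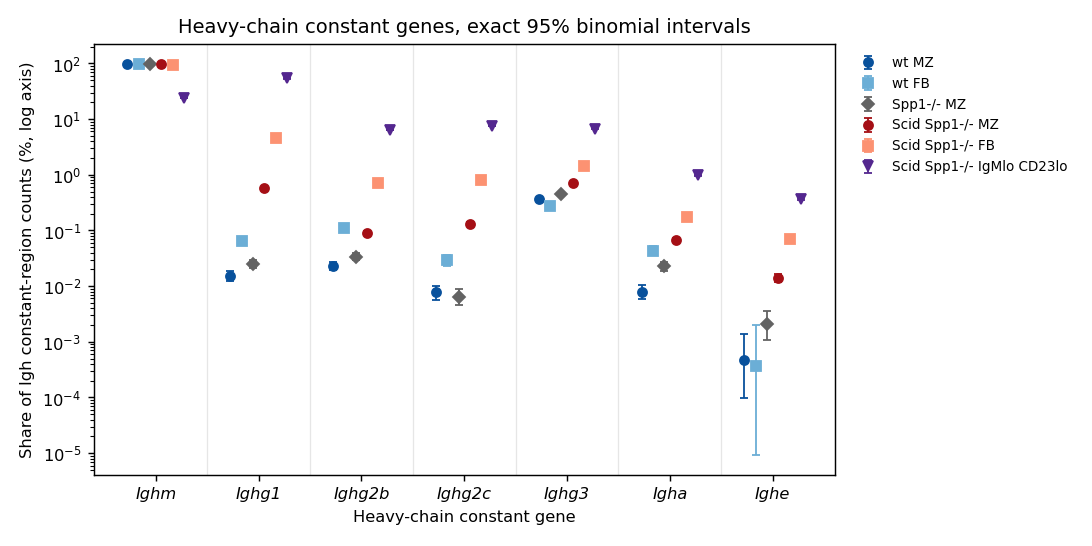
Share of heavy chain constant reads, Ighd left out (percent, log axis), taken by each constant gene in the 6 libraries, with exact binomial 95% intervals. Ighg1 ran from 0.0154% in wt MZ to 53.7% in IgMlo CD23lo.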

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

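The tests of explanations in this part were chosen after the results were seen, and none of the differences between groups listed here was itself tested. They are genes whose direct log2 ratio had opposite signs in the 2 groups, 1 library a side. Cd200, a surface glycoprotein, was 2-fold higher in Scid Spp1-/- than in wt MZ and stood at -1.14 in FB. Sdc1, the plasma cell marker CD138, stood at 1.88 in MZ and -2.33 in FB for the same ratio, and for MZ over FB at -2.51 in wt and 1.70 in Scid Spp1-/-. For MZ over FB, Aicda stood at 2.18 in wt and -2.76 in Scid Spp1-/-. The cell cycle genes Mki67 (1.40 and -1.02), Ccnb2 (1.62 and -1.52), Birc5 (2.03 and -1.18) and Ube2c (1.41 and -1.13) had the same pattern. So did Fn1, or fibronectin (3.32 and -1.18), and the granulocyte genes S100a8 (2.05 and -1.21), S100a9 (1.36 and -1.16), Ngp (1.36 and -1.23) and Camp (1.93 and -1.51), whose wt counts were few.

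Germinal centre, cell cycle and switched constant genes were high in Scid Spp1-/- FB, and cells like the IgMlo CD23lo sort in that library are a candidate source. Such cells would bring germinal centre genes at 1 share, and over the 10 measured the excess in Scid Spp1-/- FB was 6.89% of that in IgMlo CD23lo at the median, with a ratio of upper to lower quartile of 1.63. Efnb1 (32.4%) and Bcl6 (-19.4%) stood apart, and Bcl6, at 188 CPM in wt FB, 119 in Scid Spp1-/- FB and 487 in IgMlo CD23lo, went against such a share by itself, though its wt FB level could hide one of this size. The 25 proliferation genes had a share of 15.4% at the median (quartiles 13.5 to 18.3) and the 6 switched constant genes, Ighg3 included, 13.7% (10.8 to 19.2), and all 25 and all 6 lay above the upper quartile of the 9 germinal centre genes without Bcl6 (7.63), which argues against 1 such share as the whole source of either excess. In MZ the switched constant genes had 8.44% at the median and the germinal centre genes 0.667%, and cells in FB itself that divide, switch or enter the germinal centre programme stay open, as does a gate that let in part of the CD23-low cells.

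Granulocyte and erythroid genes were higher in the Scid Spp1-/- libraries, and 94.7% of 19 members that reached 1 CPM (18 of them) were above both wt libraries in all 3 Scid Spp1-/- libraries. A lower share of B cells, with more of every other cell alike, was asked about by comparing folds, T cells being left out because beads had depleted them. The lower quartile of the neutrophil list (log2 5.76) lay above the upper quartiles of the NK cell (3.58), macrophage (4.54), erythroid (4.69) and dendritic cell (4.86) lists, by 0.89 or more. Folds depend on the wt level, which differed between lists. Summed over members in wt MZ and wt FB it was 3.09 and 6.59 CPM for neutrophils, 37.7 and 6.37 for NK cells, 24.0 and 12.5 for macrophages, 16.1 and 108 for erythroid cells and 5.61 and 8.96 for dendritic cells. These folds therefore cannot decide whether other cells rose alike. Precursor cells or their free RNA cannot be told apart from expression by the B cells themselves, since any source gives the 94.7%. The median ratio of the highest to the lowest of the 3 Scid Spp1-/- sorts, 2.28 over 6 neutrophil members, left both open as well. Sorting on CD19 and B220 is meant to remove granulocytes and erythroid cells, but how fully it did so was not measured. It does not bear on free RNA. Mpo (155 CPM) and Hbb-bs (65.3 CPM) were the most abundant of these genes in Scid Spp1-/- MZ, and precursors in these spleens were not counted.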

How the results depend on the processing

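Depth limited genes under about 3 counts, and 1 residual degree of freedom limited every test. No paired analysis was possible by mouse because the labels carry no replicate numbers, and the genotype term compared MZ with FB within genotype. Without any of the wt or Scid Spp1-/- MZ or FB libraries no residual degree of freedom is left, and only direct comparisons remain. Without a lone library, MZ versus FB gave 562 to 611 genes and Scid Spp1-/- versus wt 501 to 574, and with neither 586 and 517. Of 6312 fitted values of 618 named or list genes by comparison under an alternative, 5595 kept direction and side of the threshold, 677 lost the call, 25 gained one, 9 that had not passed changed sign at a small size and 6 reversed. Reads recovered from the scaled table and the subtraction of the IgMlo CD23lo share were chosen after seeing the data. Except as said, the cause was not tested.

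MZ versus FB (599 genes) gave 989 with DESeq2, 1045 with limma-voom, 396 with the share subtracted, 377 with upper quartile scaling, 152 with glmTreat and 38 with no genotype term and no IgMlo CD23lo library, against 611 without that library alone. Scid Spp1-/- versus wt (556) gave 1164 with DESeq2, 1372 with limma-voom, 989 with no filter, 292 with upper quartile scaling, 282 with the share subtracted, 174 with glmTreat (136 higher, 38 lower) and 0 with no sort term over 4 libraries in edgeR, with 1681 at an unadjusted p under 0.05, against 517 there with the term. Spp1-/- versus wt (0, with 288 at an unadjusted p under 0.05 in edgeR) gave 14 with DESeq2, 1 with limma-voom and 1 with no filter. Scid Spp1-/- versus Spp1-/- (11, 54.5% higher) gave 151 with DESeq2, 27 with no filter, 7 with upper quartile scaling, 7 with recovered reads, 4 with the share subtracted, and with immunoglobulin genes removed 3 higher and 5 lower (37.5% higher), since 3 of the calls were such genes. IgMlo CD23lo gave 1457 against FB and 2125 against MZ with glmTreat, which asks for a larger change.

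With the share subtracted, MZ versus FB reversed for Aicda (3.20), Basp1 (0.58), Gcsam (0.43) and Nuggc (1.51), and Scid Spp1-/- versus wt for Aicda (-1.20) and Basp1 (-0.19), which the subtraction brings about by itself, since these genes helped set the share, their own excess lay under it, and it left 0 counts of Aicda, Gcsam and Nuggc and 16 of Basp1 in that library. Direct counts with a CPM minimum of 1 were 1199 and 1135 for MZ over FB in wt and Scid Spp1-/-, 1090 and 1329 for Scid Spp1-/- over wt in MZ and FB, 144 for Spp1-/- over wt and 793 for Scid Spp1-/- over Spp1-/-. The MZ to FB correlation was 0.739 at 20 CPM or more. By inverse Simpson, ratios of effective V segment numbers were 0.936 (Scid Spp1-/- over wt MZ), 0.831 (FB) and 0.718 (IgMlo CD23lo over Scid Spp1-/- FB) for Ighv, against 0.990, 0.904 and 0.862, and 1.22 and 0.486 for Igkv in MZ and IgMlo CD23lo, against 1.07 and 0.646. Ighg1 ratios by CPM without immunoglobulin genes in the total were 67.8, 99.7 and 11, against 38.0, 70.8 and 11.8 by share.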

Other observations

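The tests in this part were chosen after the results were seen. A few genes stood apart between genotypes in all libraries of a kind. Zhx2 (chromosome 15) was at 12.7 and 18.3 CPM in the wt MZ and FB libraries and between 76.7 and 115 CPM in the 4 libraries labelled Spp1-/-. Arl2bp (chromosome 8) was at 123 and 118 CPM in wt and between 12.4 and 17.7 in the same 4 libraries, and Gbp4 (chromosome 5) at 95.5 and 80.3 against 18.4 to 36.6. Acot9 and the processed pseudogene Gm8730 were under 1 CPM in the 3 Scid Spp1-/- libraries alone, Gm8730 going from 137 CPM in wt MZ and 154 in Spp1-/- MZ to 0.913 in Scid Spp1-/- MZ. Reads of Gm8730 may be shared with near copies, so a loss of the gene itself is not shown.

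Strain sequence carried along with the Spp1 mutation may account for part of this, as 2 of 43 expressed genes within 5 Mb of Spp1 (4.65%), Abcg3 and Gbp4, differed at least 2-fold between Spp1-/- and wt MZ, against 0.289% of 9340 genes elsewhere (one-sided Fisher exact p = 0.0077). Abcg3 (104935057 to 104982718) and Gbp4 (105115767 to 105139586) lie close together, and both were seen to differ beforehand. That p-value treats genes as independent, with 1 library a side, and so cannot settle the question. Of the 29 genes that differed, 6.90% lay within 5 Mb and 10.3% anywhere on that chromosome, so most were not themselves in sequence linked to Spp1. Likewise, of 413 genes that differed with the combined genotype, 0.726% lay within 5 Mb of Prkdc and 2.42% anywhere on its chromosome. Effects of carried sequence on genes of other chromosomes, and strain differences elsewhere in the genome, stay open. Zhx2 is known to be reduced by a mutation of the BALB/cJ substrain, and which substrain each group came from is not given.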
